A study of Drosophila melanogaster with 4 samples.

How the data were processed

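Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of the strain y; cn bw sp with a rabbit polyclonal antibody raised against Fruitless (Fru), a transcription factor with a BTB domain and zinc fingers. Per the labels, the series holds 2 ChIP libraries and 2 libraries of input DNA, that is, chromatin DNA sequenced without immunoprecipitation. The developmental stage in the labels is 0 to 8 h, whereas the collection steps in the labels' protocol speak of an egg laying of 8 to 16 h; the stage label is used here, and the difference could not be settled. Per the labels' protocols, embryos were cross-linked for 15 min in 1.8% formaldehyde.

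The values come from 1 peak list for the whole series. Per the file headers it is in FlyBase Release 5 coordinates and its peaks were called with MACS. The submitters' processing notes name BWA, MACS2, CASAVA 1.7.0.2, CASAVA 1.7.0.3 and the build BDGP5. The score that the authors deposited with each peak has no stated scale: whether it is a fold enrichment, a p-value or a q-value on a log scale is not given in the sources used here, so it served only to rank and filter peaks within this list. The other columns the authors deposited are the first and last base of each peak, in bp. Whether replicates were pooled before peak calling, which libraries entered the call, the peak threshold and any filters are not given in the sources used here. The list holds no value per library, so neither read depth nor agreement between replicates could be assessed, and the depth behind each peak is unknown. All tests therefore compare peaks or windows of the genome within 1 list; their p-values measure the spread between peaks or windows, not between embryo collections.

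The gene table used with this series is of Release 6, so its coordinates were not set against Release 5 peaks and no peak was assigned to a gene. The comparisons that need gene positions or sequence of Release 5 (peaks at transcription start sites, scores at promoters, gene lists, motifs and the fru locus) had been planned before the data were examined and were not analysed here. Peaks are named by coordinates instead. By the rule fixed before the data were examined for this situation, the 25 highest-scoring peaks on the major arms are summarised and the top 5 given in full, together with the 50 kb windows that hold the most peaks.

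Peaks were grouped by the sequence they lie on: the 6 major arms X, 2L, 2R, 3L, 3R and 4, the heterochromatic scaffolds, the unplaced scaffolds U and Uextra, and the mitochondrial genome. Arm lengths of Release 5 were not used here; the length of an arm was taken as the span from its first to its last peak. The number of peaks per arm was compared with the number expected from that span by an exact two-sided binomial test with Benjamini-Hochberg adjustment over the 6 arms, and intervals on peaks per Mb are exact 95% Poisson intervals that cover counting error only. Because that test treats neighbouring peaks as independent, X and the large autosomal arms were also compared over whole 1 Mb windows laid from the first peak of each arm. That comparison, and those of scores between groups of peaks, used two-sided permutation tests with 100000 draws, for which 1e-05 is the smallest p that can be given. Intervals on differences of means or ratios over windows come from 10000 bootstrap draws and those on differences of median scores from 2000 draws. Clustering was measured as the median distance between neighbouring peak centres and compared with 1000 random placements of the same number of points on each arm, for which 0.002 is the smallest two-sided p that can be given. The comparisons of windows and scores between X and autosomes, of clustering with random placement, of score with width, of the strongest peaks on X (score cuts of 50, 100, 150 and 200 and the 25 highest), and of sequences outside the major arms were added after the list had been seen.

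Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The arm test was tested on simulated data: with 5339 peaks per draw and X at a simulated ratio of 0.7 to the other arms, X was called lower in 200 of 200 draws with a mean recovered ratio of 0.70, and with even density at least 1 arm was called in 8 of 200 draws. These draws placed peaks independently, whereas the real peaks are clustered, so they do not give the rate of false calls for these data. Alternatives tried were the 50% and the 25% of peaks with the highest score, peaks closer than 1000 bp merged, another arm length, and arms without their densest 1 Mb window.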

Results

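To map where Fru binds in the embryo, ChIP DNA recovered with an anti-Fru antibody and input DNA were sequenced from 2 libraries each, and the authors' peak list gave the regions called as peaks. The fruitless gene is known for its role in the male courtship circuit and also makes products that are not specific to males. The list held 5538 peaks that together covered 2875 kb. Of these, 5339 lay on the major chromosome arms, 167 on the unplaced scaffolds U and Uextra, 10 on heterochromatic scaffolds and 22 on the mitochondrial genome. There were no values per library, so errors below are spreads over peaks or windows.

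On the major arms most Fru peaks were short and low in score, and a small set was broad and high. The median width was 378 bp (quartiles 262.5 and 621 bp, n = 5339), and the peaks covered 2.41% of the 116 Mb between the first and last peaks of the arms. The authors' score, whose scale is not stated, had a median of 12.22 and quartiles of 9.93 and 16.57. A score over 100 was reached by 58 peaks, 1.09% of the total (95% Wilson interval 0.841% to 1.40%), and these accounted for 5.26% of the bases covered. Their median width was 2341.5 bp, against 374 bp for the other peaks. They were found on 5 of the arms, with 13 on 2L, 12 on 3L, and 11 each on X, 2R and 3R, and with 0 of the 12 peaks on chromosome 4.

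The highest score on the arms, 509.52, belonged to a 9269 bp peak on 3L from 6175490 to 6184758 (Release 5), which was also the widest of the list. The second, 456.57, was on 3R from 26737332 to 26739755, and the third, 406.38, on X from 9576519 to 9581387. A peak on 2R from 9076230 to 9079675 scored 394.60, and one on 2L from 6086833 to 6090082 scored 378.68. The 25 highest-scoring peaks all reached at least 238.58 and had a median width of 2754 bp. Among them, 8 lay on 2L, 6 on 3R, 5 on 2R, 5 on 3L and 1 on X.

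Score and width rose together across the 5339 peaks, which are not independent replicates. Spearman's rho was 0.70 (permutation p = 1e-05) and Pearson's r on log10 values was 0.71 (permutation p = 1e-05). Without the 2 widths farthest from the median, r was 0.71.

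**Figure D1:**
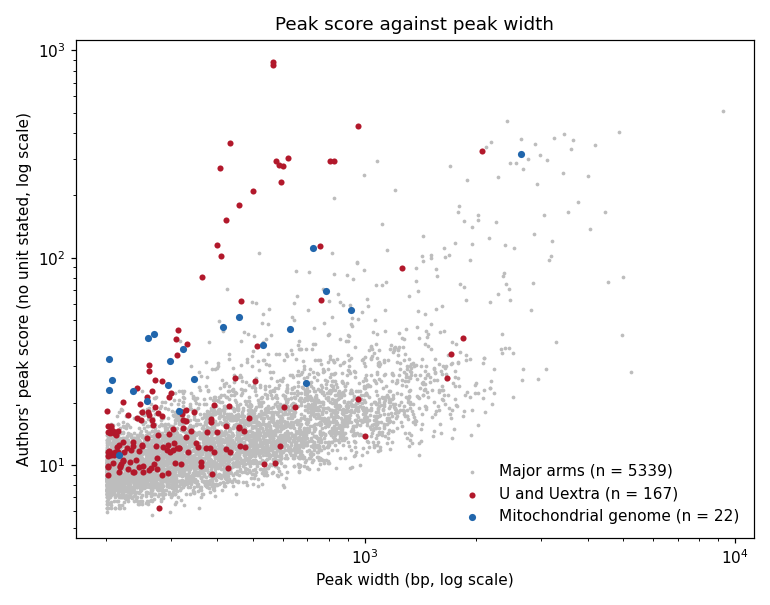
The authors' score of each peak (no unit stated, log scale) is plotted against its width in bp (log scale), with 1 point per peak for the major arms (grey, n = 5339), U and Uextra (red, n = 167) and the mitochondrial genome (blue, n = 22). Grey points rise with width, and a set of red points stands above the grey ones of the same width, up to a score of 876.73 at 564 bp.

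Fru peaks were unevenly divided among the arms. Arm 2R was the densest, with 1212 peaks or 62.0 per Mb (95% Poisson interval 58.5 to 65.6), and 3R followed with 1424 peaks or 51.1 per Mb (48.5 to 53.9). Arms 3L and 2L held 42.8 (40.2 to 45.5) and 41.7 per Mb (39.1 to 44.5). The X held 706 peaks, 33.9 per Mb (31.5 to 36.5), and the small and largely heterochromatic chromosome 4 held 12 peaks, 12.8 per Mb (6.59 to 22.3). Set against the number expected from each span, the ratio was 1.35 for 2R (exact binomial test, adjusted p = 2.73e-27), 1.11 for 3R (adjusted p = 7.91e-06), 0.737 for X (adjusted p = 4.45e-20) and 0.278 for chromosome 4 (adjusted p = 8.17e-08). The ratios of 0.907 for 2L (adjusted p = 0.000966) and 0.931 for 3L (adjusted p = 0.00912) were closer to 1 in the same exact test, and no longer passed the threshold once peaks closer than 1000 bp were merged (adjusted p = 0.221 and 0.12). This test counts neighbouring peaks as independent, which makes its p-values too small.

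The X also differed from the autosomes when windows were the unit of comparison. The mean number of peaks per 1 Mb window was 34.4 ± 18.2 on X (SD, n = 20 windows) and 49.3 ± 17.5 on 2L, 2R, 3L and 3R together (SD, n = 92 windows). The difference, X minus autosomes, was -14.9 (95% bootstrap interval -23.1 to -5.84), and few random regroupings of windows gave one as large (permutation p = 0.00083). The autosomal arms differed among themselves, with means of 42.7 on 2L, 43.25 on 3L, 51.3 on 3R and 61.9 on 2R. The size of the difference therefore depends on pooling them, and X was not tested against single arms. Neighbouring windows were counted as independent. Scores were lower on X as well: the median was 11.22 for its 706 peaks and 12.42 for the 4621 autosomal peaks, a difference of -1.20 (95% bootstrap interval -1.49 to -0.69, permutation p = 1e-05). This test counts clustered peaks as independent. With peaks closer than 1000 bp merged, the difference was -0.9 (permutation p = 0.00575). Peaks on X were also narrower, with a median of 340.5 bp against 371.5 to 397.5 bp on the large autosomal arms, and scores were not compared at equal width. Among peaks with scores up to 9.93, the lowest 25%, 15.3% were on X (205 of 1339, 95% Wilson interval 13.5% to 17.3%), against 10.8% among those from 16.59 up, the highest 25% (141 of 1310, 9.20% to 12.6%; Fisher's exact test, two-sided p = 0.000534). Among the strongest peaks the comparison passed the test at none of 5 cuts. The intervals were wide and overlapped, so no dependence on the cut was shown among these 5. Over a score of 50, X held 24 peaks and the 4 large autosomal arms 97. That is a ratio per Mb of 1.12 (exact 95% interval 0.686 to 1.77, exact binomial test, adjusted p = 0.833). The shortfall of X in the highest 25% of peaks was thus not seen over 50, and the change between them was not tested. Over a score of 100, X held 11 peaks and the 4 large autosomal arms 47, a ratio per Mb of 1.06 (exact 95% interval 0.496 to 2.07, exact binomial test, adjusted p = 0.864). Of the 25 highest-scoring peaks X held 1 and those arms 24, a ratio of 0.189 (0.00459 to 1.16, exact binomial test, adjusted p = 0.186). The windows of X held from 12 to 86 peaks, with a median of 30. The densest ran from 19412622 to 20412621, and it was not tested against the other windows.

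**Figure D2:**
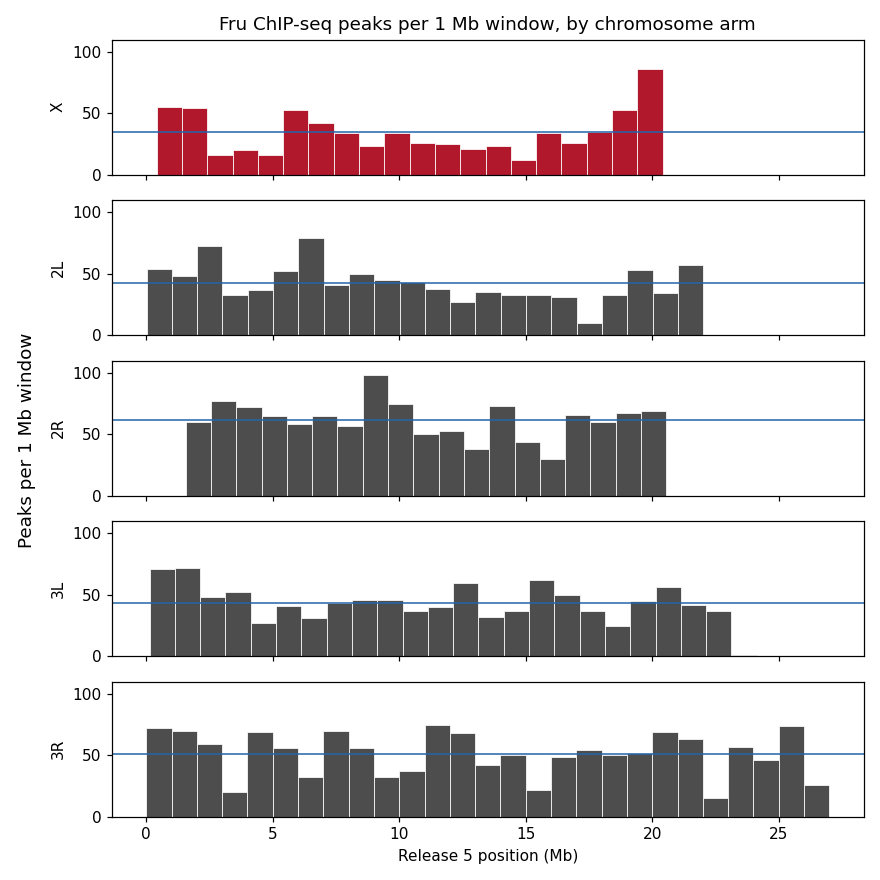
The bars give the number of Fru peaks in each whole 1 Mb window along X (red) and the 4 large autosomal arms (grey), against Release 5 position in Mb, and the blue line is the mean over the windows of each arm. The mean is 34.4 on X and between 42.7 (2L) and 61.9 (2R) on the autosomal arms, and the tallest bar on X holds 86 peaks.

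The peaks lay in clusters on the 5 large arms. Over all arms the median distance between neighbouring peak centres was 3642.5 bp, whereas random placement of the same number of points gave a median of 14649 bp (range 14101 to 15473 over 1000 placements, permutation p = 0.002, the smallest they can give). The observed distance was 0.249 of the random one, and 0.45 of it after peaks closer than 1000 bp were merged. Arm by arm the ratio ran from 0.186 on X to 0.312 on 2R (permutation test, adjusted p = 0.0024 for X, 2L, 2R, 3L and 3R), while the 12 peaks of chromosome 4, with a ratio of 0.478, did not pass (permutation test, adjusted p = 0.0819). With the 25% of peaks of highest score the ratio was 0.535, and random subsets of the same size gave a median of 0.53. In 50 kb windows laid from base 1 of each arm, 1030 of 2370 (43.5%) held no peak, against 10.6% for a Poisson distribution with the same mean of 2.25 peaks per window. The variance was 4.29 times the mean. Windows before the first peak of an arm are empty by definition, and the Poisson value takes the same mean for arms of unequal density. Both add to the excess of empty windows, which is therefore not due to clustering alone. Of the gaps between neighbours, 1768 of 5333 (33.2%) were shorter than 1000 bp. Merging across these left 3571 regions, of which 1145 held several peaks and the richest held 9.

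The densest 50 kb windows were on 2R from 4500001 to 4550000 and on 3R from 21850001 to 21900000, with 21 peaks each. Next came a window on 2R from 8800001 to 8850000 and one on 3R from 12050001 to 12100000, with 20 each. A high peak number did not go with high scores in each of them. The 3R window at 21850001 contained a peak of score 360.38, while the highest scores in the others were 31.5 (2R at 4500001), 63.54 (2R at 8800001) and 34.06 (3R at 12050001), with medians between 10.29 and 12.76 in all 4.

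Peaks on the unplaced scaffolds and the mitochondrial genome scored higher than those on the major arms. On U and Uextra, which collect sequence that Release 5 did not place on a chromosome, the median score was 14.49 (quartiles 11.55 and 21.19, n = 167), 2.27 above the arms (95% bootstrap interval 0.53 to 3.29, adjusted permutation p = 1e-05). A score over 100 was reached by 19 of these peaks, 11.4% (95% Wilson interval 7.41% to 17.1%), compared with 1.09% on the arms (Fisher's exact test, adjusted p = 1.14e-12). Both tests count the peaks on U and Uextra as independent, and whether some lie on copies of the same sequence was not examined. The 2 highest scores of the whole list were there: 876.73 for a 564 bp peak on Uextra from 22939296 to 22939859, and 852.22 for a 567 bp peak on U from 2605796 to 2606362. On the mitochondrial genome, which lies outside the nucleus, the median score was 34.36 (quartiles 24.6 and 46.4, n = 22), 22.1 above the arms (95% bootstrap interval 13.1 to 33.0, adjusted permutation p = 1e-05), and 21 of the 22 peaks exceeded the median of the arms. These 22 peaks covered 57.3% of the stretch from 13 to 19615. The test counted them as independent although they are neighbours on a single sequence, which makes its p-value too small and its interval too narrow. The highest of them, 315.51, extended from 16964 to 19615, at the end of the numbering.

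**Figure D3:**
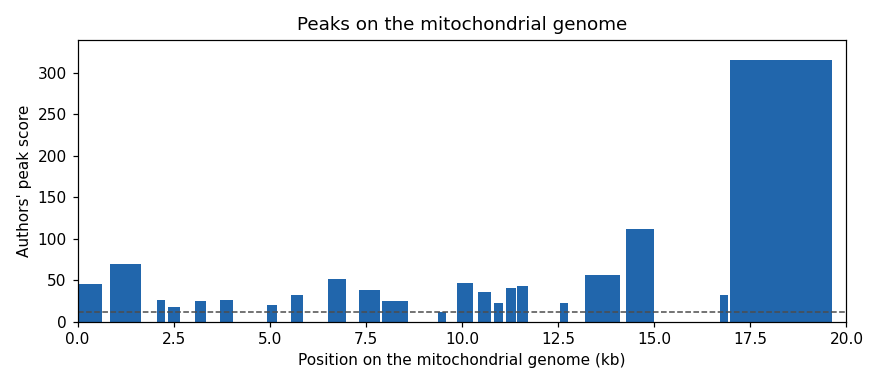
Each bar is a peak on the mitochondrial genome, drawn over its position in kb, with the authors' score as its height, and the dashed line is the median score of the major arms (12.22). The 22 peaks are spread over the whole length, 21 of them rise above the line, and the tallest, 315.51, is the last.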

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

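The tests in this part were chosen after the scores had been seen. Signal in sequence outside the chromosome arms was found in 3 places: 22 peaks on the mitochondrial genome, 167 on the unplaced scaffolds U and Uextra, and 10 on the heterochromatic scaffolds. The last had a median score of 12.94, with 0 of 10 over 100 (95% Wilson upper bound 27.8%). In the list as a whole, 9 of the 25 highest-scoring peaks lay outside the major arms.

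A candidate explanation for the high scores is that sequence with many copies raises the score of a peak of a given width, since reads from every copy fall on the few copies in the assembly. Input reads would collect there in the same way, and how far the score corrects for this is not given. Among peaks 300 to 1000 bp wide, the median was 18.3 outside the arms (n = 93) and 13.56 on them (n = 2975), a difference of 4.74 (95% bootstrap interval 2.57 to 12.5, permutation p = 1e-05). The 93 peaks pool U and Uextra, the heterochromatic scaffolds and the mitochondrial genome, and none of these was compared alone at such widths. The comparison shows only that, for this pool, the difference is also there at similar widths. The higher scores had prompted the comparison, and copy number was not measured. Strong binding of Fru to such sequence stays open as well. For the mitochondrial genome, a higher amount of its DNA in the ChIP than in the input libraries could also give peaks along its length. Peaks covered 57.3% of the span, between a mark of at least 90% set for this explanation and a mark under 10% set against it. Both marks were chosen after the scores had been seen, and the cover that such an excess would give is not known. This explanation therefore cannot be told apart from peaks at separate sites.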

How the results depend on the processing

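With all peaks the major arms hold 5339 peaks of median width 378 bp; keeping the 50% with the highest score leaves 2670 by construction and raises the median width to 582.5 bp, and the 25% leaves 1335 with a median of 780 bp. The lower density of 2L lost its call with the top 50% of peaks (ratio 0.945), the top 25% (0.937) and peaks closer than 1000 bp merged (0.957). That of 3L lost it with the top 50% (0.927) and with merging (0.946). With the top 25%, 3L kept its call (ratio 0.891, exact binomial test, adjusted p = 0.0482). The ratios of 2L and 3L stayed below 1 throughout, and the cause of the lost calls was not tested. In the other 37 tested results under alternatives the direction and the side of the threshold stayed as reported, and none reversed; for X the ratio ranged from 0.593 (top 25%) to 0.739 (length from base 1 to the last peak), and without the densest 1 Mb window of each arm it was 0.705. The ratio for chromosome 4, with 12 peaks, ranged from 0.185 to 0.346. The observed median distance between neighbours was 0.249 of the random one with all peaks, 0.373 with the top 50%, 0.535 with the top 25% and 0.45 with merging. Random subsets of the same sizes gave medians of 0.37 and 0.53 (100 subsets each, ranges 0.344 to 0.399 and 0.473 to 0.587), so that no effect of the score beyond that of fewer peaks was seen. The alternative lengths, the arms without their densest window, and all alternatives for windows, scores and clustering were chosen after seeing the data. The expected number per arm from start sites, and all alternatives for start sites, promoter scores, gene lists, motifs and the fru locus, were not run, as positions of genes and sequence in Release 5 were not used here. No paired analysis was possible because the list holds no value per library, and for the same reason leaving out a replicate was not run. Read depth per library is unknown, so it cannot be said which regions lacked the depth to be called.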

Other observations

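When peaks were read along the arms, 2 stretches stood out. On 3R, around the dense window that starts at 21850001, 36 peaks lay between 21809120 and 21881124. Of these, 2 scored over 100 (292.67 from 21856164 to 21857244, and 360.38 from 21867188 to 21869382), while the other peaks had a median of 13.5 and none above 38.33. On 2L, 41 peaks between 21400000 and 21550000 had a median score of 11.17 and none above 20.85. The authors' scores also repeat: 20 values are each shared by at least 50 peaks, and 1516 peaks (27.4%) hold 1 of these 20 values, the most frequent being 9.02 with 93 peaks.

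The test of spacing on 2L and that of the strongest peaks on X were chosen after the values had been seen; the test of copy number on X was set before its ratio was known, though after the median scores were. In the 2L stretch, peak centres seemed to recur at even steps. Steps from 3000 to 8000 bp were scanned, and a step of 5000 bp gave the largest excess, with 46 pairs of centres at a multiple of it against 23.6 expected, above 99.1% of 1000 random placements of 41 peaks in the same stretch. As the stretch was picked for its even spacing, this value describes the pattern and is not independent evidence for it. A tandem repeat in this stretch is a candidate explanation that was not tested here, since neither sequence nor copy number was examined.

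The lower number and score of peaks on X may reflect a lower copy number of X in a collection of both sexes. That would lower the ChIP signal there, and the labels give the sex as unknown. Input DNA from such embryos would share that copy number, and how far the score corrects for it is not given. With scores on X raised by 4/3, as equal numbers of both sexes would need if the score grew in proportion to copy number, and a floor of 10.7 for all arms, the ratio of peaks per Mb between X and the autosomes was 0.956 (95% bootstrap interval 0.755 to 1.19). Without the factor and at the same floor it was 0.603 (0.476 to 0.752). Raising the scores on X at a fixed floor can only raise this ratio, whatever the cause, so the rise does not tell the causes apart. The strongest peaks did not decide it: over a score of 100 the ratio was 1.06 where the same factor would give 0.745, and for the 25 highest it was 0.189 where the factor would give 0.458, and the exact 95% intervals of 0.496 to 2.07 and 0.00459 to 1.16 hold both the value from the factor and 1. The copy number hypothesis, which also rests on an assumed scaling of a score whose scale is not stated, and a lower density of Fru sites on X both stay open.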
